A study of Mus musculus with 4 samples.

How the data were processed

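RNA sequencing libraries were prepared from total RNA of a mouse pancreatic ductal adenocarcinoma cell line with the RNeasy and TruSeq RNA Sample Prep kits, per the labels' protocols. The 4 libraries fall into 2 groups of 2, labelled EtOH and 4-OHT, with a replicate number in each title. Bowtie2 version 2.2.6.2, HTSeq, DESeq2 version 2.11.39 and the mm10 build are named per the submitters' processing notes, without their roles or order. The gene annotation, the strand setting of the counting and any filter on reads are not given in the sources used here. The first deposited table holds raw counts per gene symbol, as whole numbers, for 23420 genes and 4 libraries. The second deposited table holds the same counts divided by 1 size factor per library, a normalised signal that the authors deposited beside them. These factors, 1.08, 0.839, 1.01 and 1.10 for EtOH replicates 1 and 2 and 4-OHT replicates 1 and 2, equalled the DESeq2 median-of-ratios factors of the raw counts.

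Columns were assigned to libraries by their headers. In each group 1 column carries the number 2 and the other carries no number, so the unnumbered column was taken as replicate 1. Among the symbols of the raw counts, 14 were held as calendar dates, and all 14 were restored from the normalised table by their values. No gene symbol was repeated and no row lacked a gene name. Total counts ran from 11000349 to 14678732 per library. Libraries of the same group differed far beyond counting error, with a chi-square per degree of freedom of 31.5 between the EtOH libraries and 36.8 between the 4-OHT libraries, so none was a repeated deposit and precision was set by the spread between libraries. The labels do not say that the replicates came from separate cultures, so p-values of single genes measure only the spread between these samples, which may be technical.

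Genes were tested with the quasi-likelihood method of edgeR version 4.0.16 in R version 4.3.3 on the raw counts, two-sided, with TMM scaling, group as the only term and Benjamini-Hochberg adjustment at 0.05. The edgeR filter on low counts (minimum count 10, minimum total 15) left 11984 genes. Fold changes are given as log2 values of 4-OHT minus EtOH with the standard error (SE) of the model. Normalised counts per library are those of the deposited normalised table. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so none is reported.

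The contrast, the test, the rule for naming genes, the alternatives and 32 gene lists were fixed before the data were examined. The lists covered 931 different genes; 924 were found by symbol and 7 by an older symbol. Lists were tested with camera of limma version 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 32 lists. Camera compares a list with the other genes tested. Its p-value rests on how the gene statistics spread over genes and on the preset correlation. A small value therefore does not measure agreement between replicate libraries. Adjusted p-values of lists are from this test unless another is named. The same test with an estimated correlation and the fry test, which asks whether the genes of a list move on balance in 1 direction, were alternatives. Within each list, gene p-values from edgeR were also adjusted over the list alone. Counts of members that passed are those of edgeR unless another test is named.

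The fixed rule named Mtor and, among genes past the threshold, the 10 highest and 10 lowest fold changes with a mean of at least 100 normalised counts and no overlap between the groups, followed by up to 3 called members of each called list. No gene passed the threshold. The other genes named were therefore chosen after the values were seen, by the same rule with an unadjusted p under 0.05 in place of the adjusted one, or as further members of a fixed list. Gene positions are those of the GENCODE annotation release M21 on the same mouse assembly, which was matched by symbol; it was not stated to be the annotation used for counting.

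Alternatives were RLE and upper-quartile scaling, a stricter filter (1 CPM in 2 libraries), no filter, DESeq2 version 1.42.0, limma with voom weights, the replicate number as a term, and each library left out in turn. After the data were seen, a correction for GC content and transcript length (splines with 5 degrees of freedom, 11872 genes with a value), camera after upper-quartile scaling and camera without the filter were added. The procedures were tested on simulated data with the means and depths of these libraries and 200 changed genes of 11984. At the estimated spread, edgeR recovered 51 of 100 genes changed 2-fold and 97 of 100 changed 4-fold, and 8 of its 156 calls were unchanged genes. The simulated spread followed abundance alone, without spread particular to a gene or a difference between the replicate numbers. These shares therefore do not tell how many real changes of that size were missed. For the list tests, 20 lists of independently varying genes were simulated, 5 of them shifted by -0.50. Camera with the preset correlation called 5 shifted lists and 0 others. Camera with an estimated correlation called 0 lists, and fry called 5 shifted lists and 1 other.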

Results

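RNA abundance was measured in a mouse pancreatic cancer cell line that carried a Pdx1-driven Flp recombinase, an Flp-activated Kras allele, a CreERT2 recombinase at Rosa26 and floxed Mtor alleles. CreERT2 enters the nucleus and recombines lox sites when bound by tamoxifen derivatives. EtOH and 4-OHT are the usual short forms of ethanol, a solvent, and 4-hydroxytamoxifen. The 2 libraries labelled EtOH held 13378718 and 11000349 gene counts, and the 2 libraries labelled 4-OHT held 12335321 and 14678732. Between 14056 and 14667 genes had at least 1 count per library, and the 10 most abundant genes took 4.40% to 4.91% of the counts. The design states 1 contrast, deletion of Mtor induced by tamoxifen, here set against the solvent.

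Mtor, the kinase shared by the mTORC1 and mTORC2 complexes (chromosome 4, 148448611 to 148557683, plus strand, mm10), was not lower in the libraries labelled 4-OHT. Its normalised counts were 780 and 833 in EtOH replicates 1 and 2 and 931 and 1149 in 4-OHT replicates 1 and 2. The means were 806 ± 37.6 and 1040 ± 155 (SD, n = 2 each), a log2 fold change of 0.37 (SE 0.16; 95% interval -0.03 to 0.77; edgeR adjusted p = 0.594). The value was 0.21 without 4-OHT replicate 2 and 0.18 after a correction for GC content and length. The labels do not name the deleted exons, and the longest annotated Mtor transcript has 58 exons, so a count over the whole gene does not check the deletion. The groups are therefore given as labelled in every comparison. Rictor and Rptor, subunits of mTORC2 and mTORC1, had log2 fold changes of 0.27 (SE 0.13) and 0.26 (SE 0.18). Of the 10 measured mTOR complex subunits, 0 passed over all genes or adjusted over the list alone, and the list was not called (median 0.11, adjusted p = 0.174; median 0.22 without 4-OHT replicate 1, 0.18 without EtOH replicate 1 and -0.0084 after the GC and length correction).

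Of 32 gene lists, camera called 16 lower and 4 higher in the libraries labelled 4-OHT. The lower lists with the medians farthest from 0 were those of cholesterol synthesis, ATF4 targets, hypoxia targets and glycolysis. The higher lists were those of inflammatory factors, mesenchymal markers, MAPK output and lysosomal genes, and each of these 4 calls was lost without at least 1 of the libraries. With an estimated correlation 0 lists were called, and fry called 0 (lowest adjusted p = 0.205). The test with an estimated correlation also called 0 of 5 shifted lists in simulated data. It lost the glycolysis list although the estimated correlation there, 0.0027, lay below the preset 0.01. Its adjusted p-values, given below for each called list, therefore cannot decide for or against a call. Among called lists the estimate also lay below 0.01 for the pentose phosphate and acinar lists. In the other called lists it was above the preset, such as 0.71 for ribosome biogenesis, 0.67 for cholesterol and 0.33 for mitosis. Where members move together to that degree, the preset test gives p-values that are too small. In 15 of the 20 called lists the mean of the members in both 4-OHT libraries lay on the same side of both EtOH libraries, 12 lower and 3 higher. Leaving out any 1 library kept the call and direction of 9 lists: cholesterol, fatty acid, ATF4, aminoacyl-tRNA synthetase, unfolded protein response, glycolysis, hypoxia, respiratory chain and mitosis.

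**Figure D1:**
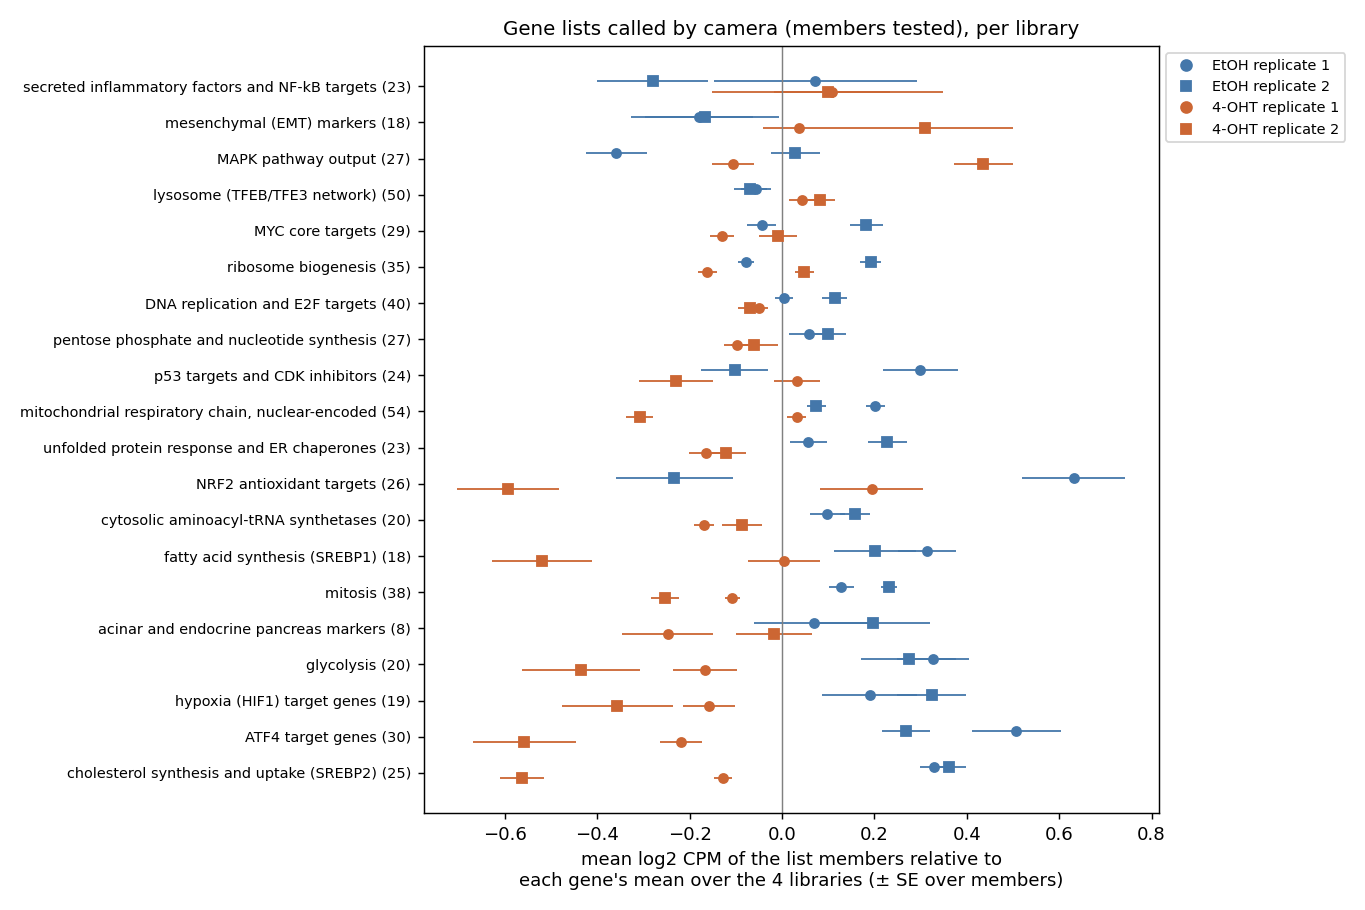
Mean log2 CPM of the members of each called gene list in each library, relative to each gene's mean over the 4 libraries, with bars for the SE over members and the number of members tested in parentheses. In the cholesterol list, the libraries labelled 4-OHT lay at -0.13 and -0.56 and the EtOH libraries at 0.33 and 0.36.

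All 25 genes of cholesterol synthesis and uptake, the set driven by the transcription factor SREBP2, had a log2 fold change below 0, and 23 were lower in both 4-OHT libraries than in both EtOH libraries. The median was -0.72 and the mean -0.67 ± 0.28 (SD over members; adjusted p = 3.88e-14). The call was lost, at adjusted p = 0.495 with an estimated correlation. By edgeR, 0 members passed over all genes and 18 passed adjusted over the list alone. The largest decreases among these were those of Pcsk9, which lowers LDL receptor levels (-1.08, SE 0.24), and Pmvk, a kinase of the mevalonate pathway (-1.04, SE 0.24). Hmgcr, the rate-limiting enzyme of the pathway, had 7234 and 7148 normalised counts in the EtOH libraries and 5003 and 3723 in the 4-OHT libraries (-0.72, SE 0.20). Srebf2 and Ldlr were among the 7 members that did not pass. Without 4-OHT replicate 2 the median was -0.48. The count adjusted over the list alone was 6 without EtOH replicate 1, 0 without EtOH replicate 2 or 4-OHT replicate 2, and 22 without 4-OHT replicate 1.

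Genes of fatty acid synthesis, targets of SREBP1, had a median of -0.32 and a mean of -0.48 ± 0.49 (SD over 18 members), and 11 were lower in both 4-OHT libraries (adjusted p = 8.71e-06; adjusted p = 0.495 with an estimated correlation). Over all genes 0 members passed by edgeR and 1 by DESeq2, the fatty acid elongase Elovl6 (DESeq2 adjusted p = 0.000126). By edgeR adjusted over the list alone Elovl6 passed (-1.36, SE 0.23, with 3420 and 3131 normalised counts against 1516 and 1029). The acetyl-CoA synthetase Acss2 (-1.41, SE 0.44) and the desaturase Scd2 (-1.02, SE 0.32) did not. Without 4-OHT replicate 1 the median was -0.58 and 5 members passed over the list, as many as without the filter on low counts.

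Target genes of ATF4, a transcription factor of amino acid metabolism and stress, had a median of -0.69 and a mean of -0.76 ± 0.62 (SD over 30 members; adjusted p = 1.65e-11; adjusted p = 0.495 with an estimated correlation). In 21 members both 4-OHT libraries lay below both EtOH libraries. By edgeR 0 passed over all genes and 13 were lower adjusted over the list alone. These included Cth, an enzyme of cysteine synthesis (-1.52, SE 0.20), Psph and Psat1 of serine synthesis (-1.25, SE 0.19, and -1.04, SE 0.20), the cystine transporter Slc7a11 (-2.05, SE 0.53), the mTORC1 inhibitor Ddit4 (-1.48, SE 0.25) and Atf4 itself. Psph shares 10.4% of its exonic length with Cct6a on the opposite strand, and the strand setting of the counting is not known. The count of 13 was 5 without EtOH replicate 1 and 8 without 4-OHT replicate 2. Ddit3, Atf3 and Slc3a2 did not pass, with log2 fold changes between -0.07 and 0.08. The 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had a median of -0.30 and a mean of -0.26 ± 0.25, with 13 lower in both 4-OHT libraries (adjusted p = 0.000102; adjusted p = 0.495 with an estimated correlation). Neither over all genes nor adjusted over the list alone did a member pass (0 and 0); Aars, which overlaps Exosc6 over 14.3% of its exonic length, had -0.66 (SE 0.16) and Tars -0.51 (SE 0.14). The unfolded protein response and ER chaperone list (23 members) had a median of -0.27 and a mean of -0.29 ± 0.27, with 13 lower in both (adjusted p = 8.61e-05; adjusted p = 0.495 with an estimated correlation). In this list 0 members passed over all genes and 0 adjusted over the list alone; the co-chaperones Sdf2l1 and Dnajb11 had -0.80 (SE 0.16) and -0.70 (SE 0.15). The number passing over this list was 2 with the stricter filter or without a filter, and 3 with upper-quartile scaling or after the GC and length correction.

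**Figure D2:**
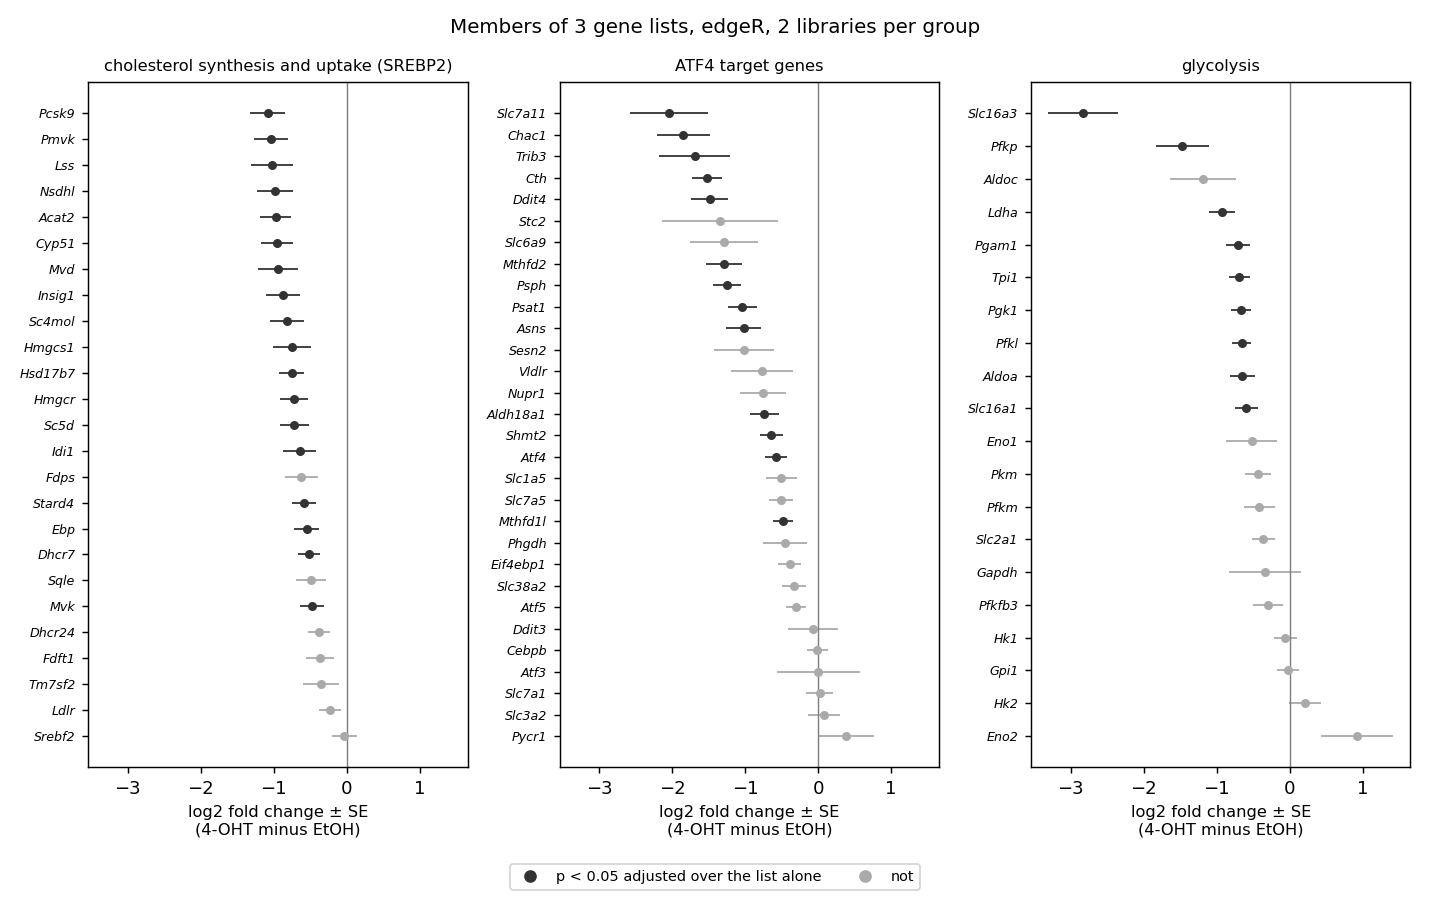
Log2 fold change (4-OHT minus EtOH, 2 libraries each) with its SE for each tested member of the cholesterol, ATF4 and glycolysis lists; dark points passed when p was adjusted over the list alone. Dark points number 18, 13 and 9, and all lie below 0.

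In the glycolysis list (20 members) the median was -0.56 and the mean -0.58 ± 0.73 (SD over members; adjusted p = 4.38e-08; adjusted p = 0.495 with an estimated correlation). In 15 members both 4-OHT libraries were lower than both EtOH libraries. Over all genes 0 passed, and adjusted over the list alone 9 were lower, among them the lactate exporter Slc16a3 (-2.83, SE 0.48; chromosome 11, 120948480 to 120960868), Ldha, which interconverts pyruvate and lactate (-0.93, SE 0.17), and the phosphofructokinases Pfkl (-0.66, SE 0.13) and Pfkp (-1.47, SE 0.36). Slc16a3 had 559 and 791 normalised counts in the EtOH libraries and 138 and 51.8 in the 4-OHT libraries. Gapdh (-0.34, SE 0.50), Hk2 (0.21, SE 0.22) and Eno2 (0.92, SE 0.50) did not pass. The count of 9 was 1 without EtOH replicate 1, 0 without EtOH replicate 2, 3 without 4-OHT replicate 1 and 2 without 4-OHT replicate 2. Hypoxia (HIF1) target genes had a median of -0.57 and a mean of -0.52 ± 0.60 (SD over 19 members), with 11 lower in both 4-OHT libraries (adjusted p = 8.61e-05; adjusted p = 0.495 with an estimated correlation). Over all genes 0 passed by edgeR and 1 by DESeq2, Loxl2. By edgeR adjusted over the list alone 4 passed. These were the ER oxidase Ero1l (-0.78, SE 0.15), the mitophagy receptor Bnip3 (-1.48, SE 0.33), the lysyl oxidase Loxl2 (-1.99, SE 0.48) and the prolyl hydroxylase P4ha2 (-0.60, SE 0.16). Bnip3 shares 22.3% of its exonic length with an opposite-strand gene. Without EtOH replicate 2 the median was -0.28 and 1 member passed over the list, and without 4-OHT replicate 2 the number was 0. It was 7 without the filter on low counts and 1 with upper-quartile scaling.

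Nuclear-encoded subunits of the mitochondrial respiratory chain were slightly lower in most members. Of 54, 53 had a log2 fold change below 0 and 32 were lower in both 4-OHT libraries (median -0.24, mean -0.27 ± 0.17, SD over members; adjusted p = 5.88e-08; adjusted p = 0.508 with an estimated correlation). Single members did not pass, 0 over all genes and 0 adjusted over the list alone; Cox5a had -0.43 (SE 0.14) and Ndufs8 -0.53 (SE 0.18). The median was -0.43 without 4-OHT replicate 1 and -0.11 without 4-OHT replicate 2.

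All 38 genes of mitosis had a log2 fold change below 0 and 27 were lower in both 4-OHT libraries (median -0.37, mean -0.36 ± 0.15, SD over members; adjusted p = 5.91e-11; adjusted p = 0.495 with an estimated correlation). By edgeR 0 passed over all genes and 0 adjusted over the list alone. The mitotic kinases Aurka and Plk1 had -0.74 (SE 0.15) and -0.51 (SE 0.14), and the spindle protein Hmmr -0.56 (SE 0.15). Genes of DNA replication (40 members) had a median of -0.13 and a mean of -0.12 ± 0.22, with 15 lower in both 4-OHT libraries and 6 higher (adjusted p = 0.0286; adjusted p = 0.508 with an estimated correlation). Of these 0 passed over all genes and 0 adjusted over the list alone; E2f2 had -0.82 (SE 0.17) and Mcm10 -0.44 (SE 0.15). This call was lost without EtOH replicate 2 (median -0.03, adjusted p = 0.401), without 4-OHT replicate 1 (0.132) and without 4-OHT replicate 2 (median -0.09, adjusted p = 0.0506).

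Lists for growth and nucleotide supply had smaller medians that depended on single libraries. For the pentose phosphate and nucleotide synthesis list (27 members) the median was -0.14 and the mean -0.16 ± 0.34, with 13 lower in both 4-OHT libraries (adjusted p = 0.0255; adjusted p = 0.495 with an estimated correlation). G6pdx, the first enzyme of the pentose phosphate pathway, had -1.31 (SE 0.24) and Paics, of purine synthesis, 0.36 (SE 0.14); 0 members passed over all genes and 0 adjusted over the list alone. G6pdx overlaps Ikbkg on the opposite strand over 13.6% of its exonic length and has a paralog, G6pd2, counted separately. Whether reads of these genes entered the G6pdx count was not tested. That call was lost without EtOH replicate 2 (median -0.09, adjusted p = 0.185) and without 4-OHT replicate 1 (adjusted p = 0.229). Over that list 1 member passed in each of these fits, without the filter and after the GC and length correction. MYC core targets (29 members; median -0.06, mean -0.14 ± 0.27; 8 lower in both) were called at adjusted p = 0.0286, with adjusted p = 0.626 with an estimated correlation. In the MYC list 0 members passed over all genes and 0 adjusted over the list alone; Ldha and Eif4e had -0.93 and -0.43 (SE 0.15), and Myc itself had 0.62 (SE 0.21). The MYC call was lost without EtOH replicate 2 (median -0.01, adjusted p = 0.751), without 4-OHT replicate 1 (adjusted p = 0.432) and after the GC and length correction (median -0.10, adjusted p = 0.0539), and the median was -0.17 without EtOH replicate 1 and -0.15 without 4-OHT replicate 2. Without the filter 1 member passed over the MYC list. Ribosome biogenesis genes (35 members; median -0.11, mean -0.12 ± 0.15; 8 lower in both) were called at adjusted p = 0.0414, with adjusted p = 0.802 with an estimated correlation. Over all genes and adjusted over the list alone 0 of them passed, and the snoRNP protein Nhp2 had -0.35 (SE 0.14). Without EtOH replicate 2 the ribosome biogenesis median was 0.04 (adjusted p = 0.760), without 4-OHT replicate 1 it was -0.05 (0.941), and without EtOH replicate 1 or 4-OHT replicate 2 it was -0.24 or -0.21.

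NRF2 antioxidant targets (26 members) had a median of -0.29 and a mean of -0.43 ± 0.59, and 24 had a log2 fold change below 0, but only 8 were lower in both 4-OHT libraries (adjusted p = 0.000286; adjusted p = 0.526 with an estimated correlation). The list mean was 0.63 and -0.23 in EtOH replicates 1 and 2 and 0.19 and -0.59 in 4-OHT replicates 1 and 2. The groups overlapped, but within each replicate number the 4-OHT library lay lower. By edgeR 0 passed over all genes and 3 adjusted over the list alone, the haem oxygenase Hmox1 (-1.46, SE 0.22), G6pdx and the aldo-keto reductase Akr1b8 (-0.97, SE 0.20). Without EtOH replicate 1 the list was not called (median -0.02, adjusted p = 0.240) and 2 members were lower and 1 higher over the list; without 4-OHT replicate 2 it was not called either (median -0.09, adjusted p = 0.0707) and 0 members passed. Without EtOH replicate 2 and without 4-OHT replicate 1 the medians were -0.55 and -0.63. Among p53 targets and CDK inhibitors (24 members), 13 were lower in both 4-OHT libraries and 2 higher (median -0.22, mean -0.22 ± 0.45; adjusted p = 0.0209; adjusted p = 0.508 with an estimated correlation). Over all genes 0 passed and adjusted over the list alone 0; the cyclin Ccng1 had -0.65 (SE 0.16) and the apoptosis regulator Bax -0.57 (SE 0.15), while the kinase Plk2 had 0.82 (SE 0.20). The p53 call was lost without EtOH replicate 1 (median -0.14, adjusted p = 0.467) and without 4-OHT replicate 2 (adjusted p = 0.132), and the median was -0.39 without 4-OHT replicate 1. Over the p53 list 1 member passed higher and 1 lower without 4-OHT replicate 1, and 2 higher and 3 lower without the filter.

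By edgeR, the 4 lists that were higher had no member past the threshold over all genes (0 in each). By DESeq2, 1 member of the inflammatory list (Tnfaip3) and 2 mesenchymal markers (Acta2 and Cyr61) passed higher, and 0 in the other lists. Secreted inflammatory factors and NF-kB targets (23 members; median 0.30, mean 0.23 ± 0.84) had 8 members higher in both 4-OHT libraries and 0 lower (adjusted p = 0.0229; adjusted p = 0.495 with an estimated correlation). Adjusted over the list alone 0 passed; the NF-kB inhibitor Tnfaip3 had 1.11 (SE 0.24), and the NF-kB subunits Relb and Nfkb2 had 0.90 (SE 0.25) and 0.85 (SE 0.31). Without EtOH replicate 2 this list was not called (adjusted p = 0.375), and its median was 0.48 without EtOH replicate 1 or without 4-OHT replicate 1 and 0.18 without 4-OHT replicate 2. Over this list 6 members passed higher and 1 lower without 4-OHT replicate 1, and 1 higher without EtOH replicate 1 or without the filter. Mesenchymal markers (18 members; median 0.27, mean 0.38 ± 1.04; 6 higher in both, 3 lower) were called at adjusted p = 0.0449, with adjusted p = 0.495 with an estimated correlation. Adjusted over the list alone 2 were higher, the matricellular protein Cyr61 (0.95, SE 0.18; 1946 and 2137 against 3409 and 4456) and the smooth muscle actin Acta2 (3.86, SE 0.82), whose normalised counts were low, 10.1 and 2.38 against 50.7 and 143. Fibronectin, Fn1, had 0.74 (SE 0.20) and S100a4 had -1.46 (SE 0.58). The mesenchymal call was lost without EtOH replicate 1 (adjusted p = 0.108; 1 member over the list), without 4-OHT replicate 2 (median -0.01, adjusted p = 0.476; 0 members), without the filter on low counts (0.0562) and after the GC and length correction (0.0643; 0 members). Without EtOH replicate 2 the median was 0.42 with 0 members passing over the list, and without 4-OHT replicate 1 it was 0.53 with 4 higher and 1 lower.

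Genes that respond to the MAPK pathway (27 members, median 0.24, mean 0.34 ± 0.32) were above 0 in 25 members, but only 9 were higher in both 4-OHT libraries. Camera called the list at adjusted p = 0.00212, with adjusted p = 0.526 with an estimated correlation. Its mean was -0.36 and 0.03 in EtOH replicates 1 and 2 and -0.11 and 0.44 in 4-OHT replicates 1 and 2. The groups overlapped, but within each replicate number the 4-OHT library lay higher. Adjusted over the list alone 0 passed; the growth factor Hbegf had 0.65 (SE 0.19), and the transcription factors Egr1 and Fos had 1.28 (SE 0.43) and 0.69 (SE 0.23). Without EtOH replicate 1 the MAPK median was 0.11 (adjusted p = 0.272) and without 4-OHT replicate 2 it was -0.04 (0.546), against 0.53 without EtOH replicate 2 and 0.51 without 4-OHT replicate 1, where 1 member passed over the list. Lysosomal genes of the TFEB and TFE3 network (50 members; median 0.12, mean 0.12 ± 0.30; 17 higher in both, 4 lower) were called at adjusted p = 0.0286, with adjusted p = 0.495 with an estimated correlation. Adjusted over the list alone 0 passed; the cholesterol-binding protein Npc2 had 0.44 (SE 0.15), the glucosidase Gaa 0.46 (SE 0.16) and the sialidase Neu1 -0.43 (SE 0.15). The lysosomal call was lost without EtOH replicate 1 (median 0.08, adjusted p = 0.240), without 4-OHT replicate 2 (median 0.03, adjusted p = 0.240), without the filter (0.0693) and after the GC and length correction (0.0507), and the median was 0.19 without 4-OHT replicate 1 and 0.18 without EtOH replicate 2.

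Markers of other cells were few. Acinar and endocrine pancreas markers (8 of 25 tested; median -0.38, mean -0.30 ± 0.26; 3 lower in both) were called lower at adjusted p = 0.0449, with adjusted p = 0.495 with an estimated correlation; 0 passed over all genes and 0 adjusted over the list alone. All 8 were acinar genes of low abundance, such as Prss2 (37.8 and 32.2 against 25.8 and 24.6 normalised counts). This call was lost when any 1 library was left out (adjusted p from 0.0816 to 0.268), with the stricter filter (0.0775), without a filter (0.411) and after the GC and length correction (0.218). Leukocyte and endothelial markers (2 of 19 tested; median 0.03, adjusted p = 0.684) and fibroblast markers (6 of 19 tested; median 0.48, adjusted p = 0.489) were not called, and 0 members passed over all genes or adjusted over the list alone. The fibroblast median was -0.0088 without EtOH replicate 1, 0.22 without EtOH replicate 2 and 0.23 without 4-OHT replicate 2. The leukocyte and endothelial median, over 2 genes, ranged from -0.70 without 4-OHT replicate 2 to 0.63 without EtOH replicate 1, and was 0.51 without the filter.

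The remaining lists were not called, and by edgeR 0 of their members passed over all genes. By DESeq2, 1 FOXO target (Fbxo32) and 1 translation factor (Eef1a1) passed higher and 1 gene of insulin and PI3K signalling (Pik3r3) lower. Autophagy genes (40 members) had a median of 0.08 (adjusted p = 0.101), receptor tyrosine kinases (16) 0.16 (0.126), the insulin and PI3K signalling list (28) -0.04 (0.275), cytosolic ribosomal proteins (78) 0.03 (0.519), interferon response genes (23) -0.17 (0.684), epithelial and ductal markers (24) 0.03 (0.684) and oestrogen receptor targets (11) 0.06 (0.863). In these 7 lists 0 members passed adjusted over the list alone. Translation factors (33) had a median of -0.01 but a mean of 0.06 and an upward camera direction (adjusted p = 0.519), with 0 passing adjusted over the list alone. FOXO target genes (20) had a median of 0.18 (adjusted p = 0.275), and 3 were higher adjusted over the list alone: the ubiquitin ligase Fbxo32 (1.58, SE 0.28), the mitochondrial kinase Pink1 (0.70, SE 0.15) and the stress gene Gadd45b (0.77, SE 0.17). The FOXO median was 0.023 without EtOH replicate 2 and 0.059 without the filter. That FOXO count was 1 after the GC and length correction, 0 without EtOH replicate 2 or 4-OHT replicate 2, 2 without EtOH replicate 1, and 2 higher and 1 lower without 4-OHT replicate 1. Other medians also depended on single libraries. They ranged from -0.26 (without EtOH replicate 2) to 0.15 (without EtOH replicate 1) for interferon response genes, from 0.066 (without 4-OHT replicate 2) to 0.44 (without EtOH replicate 2) for receptor tyrosine kinases and from -0.099 (without 4-OHT replicate 1) to 0.21 (without 4-OHT replicate 2) for ribosomal proteins. The ranges were 0.0011 (without 4-OHT replicate 2) to 0.16 (without EtOH replicate 1) for epithelial markers, -0.056 (without 4-OHT replicate 2) to 0.12 (without EtOH replicate 2) for oestrogen receptor targets and 0.088 (without 4-OHT replicate 1) to 0.17 (without EtOH replicate 1) for autophagy. They were -0.078 (without 4-OHT replicate 2) to 0.0027 (without 4-OHT replicate 1) for insulin and PI3K signalling and -0.067 (without 4-OHT replicate 2) to 0.077 (without EtOH replicate 2) for translation factors. After the GC and length correction the median was 0.071 for receptor tyrosine kinases, -0.11 for insulin and PI3K signalling, 0.095 for ribosomal proteins, 0.051 for translation factors, 0.054 for autophagy and 0.075 for epithelial markers. The epithelial median was -0.037 with the stricter filter and 0.10 without a filter. Over the list alone, 1 receptor tyrosine kinase passed higher without EtOH replicate 1 and 1 gene of insulin and PI3K signalling lower without the filter. Of the oestrogen receptor targets, 2 passed higher without EtOH replicate 1, 1 higher without the filter and 1 lower without 4-OHT replicate 1. Leaving out 1 library brought a call to receptor tyrosine kinases (without EtOH replicate 2, adjusted p = 0.0360), cytosolic ribosomal proteins (without 4-OHT replicate 2, 0.00519) and interferon response genes (without 4-OHT replicate 1, 0.0389), and the GC and length correction brought one to ribosomal proteins (0.0115).

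Among single genes with a mean of at least 100 normalised counts and no overlap between the groups, those farthest from 0 were lower in the libraries labelled 4-OHT. The genes in this paragraph were chosen after the values were seen, and none passed the edgeR test over all genes. Rasgrp3, an exchange factor for Ras-family GTPases (chromosome 17, 75435896 to 75529054), had 1168 and 1164 normalised counts in the EtOH libraries and 217 and 257 in the 4-OHT libraries, a 4.92-fold lower mean (log2 -2.30, SE 0.16). It had the smallest edgeR adjusted p, 0.188; the next was 0.539. Lower values were also found for the endocytic receptor Lrp2 (-3.34, SE 1.01; 88.5 and 553 against 13.9 and 48.2), the calpain Capn6 (-2.37, SE 0.83), the glutathione-degrading enzyme Chac1 (-1.85, SE 0.36), the Ral exchange factor Rgl1 (-1.84, SE 0.33), the lipid transporter Mfsd2a (-1.76, SE 0.30) and the pseudokinase Trib3 (-1.69, SE 0.49). Among genes within these limits, Ltbp4, a binding protein of latent TGF-beta (chromosome 7, 27305136 to 27337692), had the highest value. Its normalised counts were 540 and 358 in the EtOH libraries against 1816 and 2007 in the 4-OHT libraries (2.09, SE 0.23). Ppl, a plakin of cell junctions (chromosome 16, 5086291 to 5132421), had 1936 and 2064 against 5400 and 6280 (1.55, SE 0.16). The actin-binding protein Dbn1 (1.57, SE 0.43), the syndecan Sdc3 (1.55, SE 0.33), the cytochrome Cyp1b1 (1.54, SE 0.46), the MYC-family gene Mycl1 (1.51, SE 0.32), Synpo (1.43, SE 0.34), the mucin Muc5ac (1.42, SE 0.33) and Usp11 (1.39, SE 0.26) were also higher in both 4-OHT libraries.

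**Figure D3:**
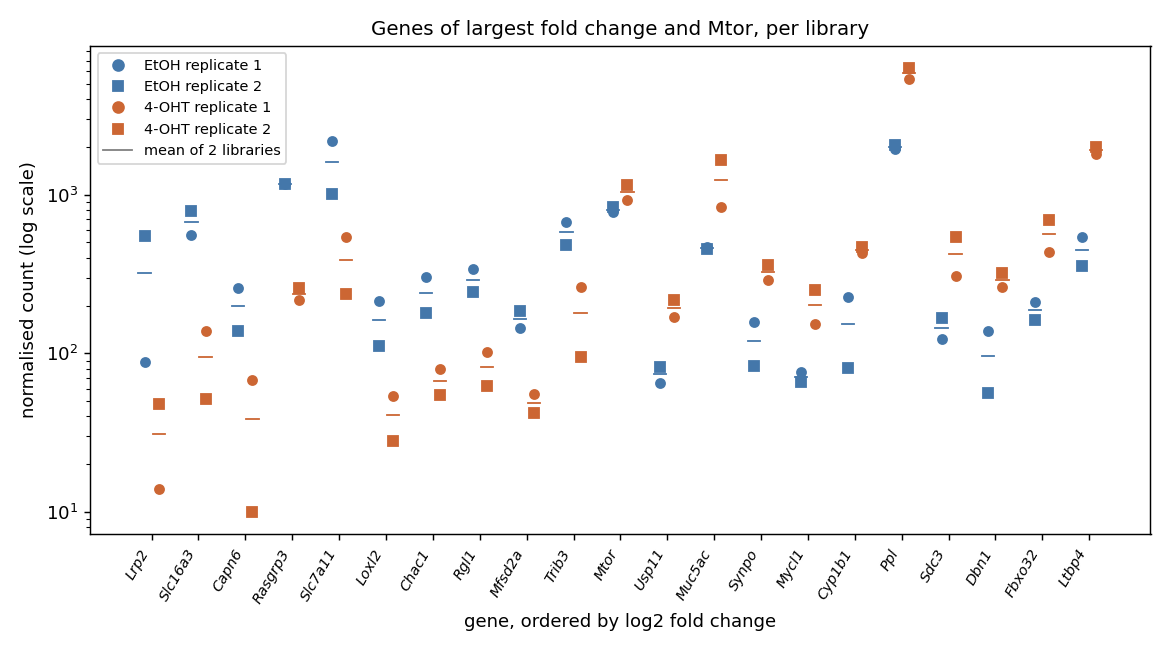
Normalised counts (log scale) in each of the 4 libraries for 10 genes of lowest and 10 of highest log2 fold change and for Mtor. Lines mark the mean of each group of 2. Apart from Mtor, the genes were ranked among those with a mean of at least 100 normalised counts and no overlap between the groups. They also had an edgeR unadjusted p under 0.05 and a symbol that is not a predicted or clone name. Rasgrp3 lies at 1168 and 1164 in the EtOH libraries and at 217 and 257 in those labelled 4-OHT, and Mtor at 780 and 833 against 931 and 1149.

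Over the 11984 genes tested, edgeR with group as the only term called 0 higher and 0 lower at an adjusted p of 0.05. Deviations from the group means correlated at 0.72 between libraries of the same replicate number, and this test counts them as error. The count of 0 therefore does not show that no gene changed. At an unadjusted p under 0.05 there were 528 higher and 476 lower, 1004 in all, where evenly spread p-values would give 599. The other splits of the same 4 libraries into 2 and 2 gave 1879, between the replicate numbers, and 2. The number of such genes therefore does not measure an effect of the treatment. DESeq2 called 31 higher and 44 lower, limma with voom weights 0 and 0, and edgeR without the filter on low counts 2 higher, Ltbp4 and Ppl, and 1 lower, Rasgrp3. By DESeq2, 9 ATF4 targets, 5 genes of the cholesterol list, 4 of glycolysis and 4 NRF2 targets were lower. So was 1 member each of the fatty acid, hypoxia, pentose phosphate, MYC, mitosis and insulin lists. Higher were 2 mesenchymal markers and 1 member each of the FOXO, translation factor and inflammatory lists. Both 4-OHT libraries lay above both EtOH libraries in 20.4% of genes and below them in 20.5%. Libraries that vary independently and alike would give 16.7% in each direction. Libraries of the same number deviated together, so that share is no exact reference.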

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

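The correction for GC content and length, camera after upper-quartile scaling and camera without the filter were chosen only after the results were seen. The named genes were chosen for groups that do not overlap, so their signs say nothing about stability. The count of genes past the threshold stayed at 0 with RLE and upper-quartile scaling, the stricter filter, limma with voom weights, the GC and length correction and each library left out. It was 2 higher and 1 lower without a filter, and 31 higher and 44 lower with DESeq2; the cause was not tested. Camera called 20 lists with RLE or upper-quartile scaling, 19 with the stricter filter, 17 without a filter (2 of them higher) and 17 after the GC and length correction (16 of the original calls). With an estimated correlation it called 0 higher and 0 lower, and fry called 0 higher and 0 lower. In simulated lists of independently varying genes, the estimated correlation recovered 0 of 5 shifts and fry 5 of 5. In the real data the estimated correlation was 0.67 for the cholesterol list and 0.48 for the respiratory chain, but 0.0027 for glycolysis. The recovery by fry does not carry over to lists whose members move together, and its missing calls were not explained. Leaving out 1 library gave 1 to 4 lists higher and 11 to 13 lower, and the ribosome biogenesis median ranged from -0.24 without EtOH replicate 1 to 0.041, a reversed sign, without EtOH replicate 2; the cause was not tested. In these fits the lone library was assumed to vary like the other group. The ribosome biogenesis mean was -0.08 and 0.19 in EtOH replicates 1 and 2 and -0.16 and 0.05 in 4-OHT replicates 1 and 2. It was thus lower with 4-OHT within each replicate number but differed more between the numbers. The alternatives on the pseudocount were not run, since raw counts were held.

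With the replicate block, the replicate number as a term, edgeR called 1179 genes higher and 1018 lower, 75 of the 75 DESeq2 calls among them, and Mtor had a log2 fold change of 0.36 (SE 0.12, adjusted p = 0.0219). Camera with the block kept 18 of the 20 list calls and lost the lysosomal (adjusted p = 0.0617) and acinar (0.0695) ones. By edgeR with the block, 22 of 25 cholesterol genes, 23 of 30 ATF4 targets and 24 of 38 mitosis genes passed lower over all genes. So did 16 of 54 respiratory chain genes, and 10 of 27 MAPK genes passed higher. In these lists 0 members passed the other way, and of the 8 acinar markers 0 passed. Deviations from the group means correlated at 0.72 between libraries of the same number, and the first principal component, with 59.0% of the variance, separated the numbers. The labels do not say what the numbers mark, and there are only 2 pairs, so this is a hint from the data and not part of the design. Depth was similar in the 4 libraries, and it limits genes of few counts such as Acta2.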

Other observations

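The tests of library scaling, of a single aberrant library and of exchanged labels were chosen only after the results were seen. The following DESeq2 calls outside the named set were chosen after their values were seen, and no function was tested for enrichment among the calls. Aldh1l2, a mitochondrial folate enzyme, had a DESeq2 log2 fold change of -2.94 (adjusted p = 1.91e-06), the adenylate kinase Ak4 -2.64 (0.000655), the ketone body enzyme Oxct1 -1.06 (0.0166) and the sterol-regulated gene Tmem97 -1.06 (0.0120). The cornified envelope gene Sprr1a had -1.32 (6.34e-05) and the water channel Aqp5 -1.17 (0.000691). The lipid droplet protein Plin4 had 2.73 (0.00595), the kinase Pim1 1.06 (0.0145) and the translation elongation factor Eef1a1 0.67 (0.0498). None of them passed the edgeR test over all genes.

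Some genes differed more within each group than between the groups. For each gene named below, the difference between replicates 1 and 2 had the same direction in both groups, so it followed the replicate number. Gsta3 had 1320 and 120 normalised counts in EtOH replicates 1 and 2 and 1332 and 73.7 in 4-OHT replicates 1 and 2. The chemokine Cxcl5 had 3378 and 342, then 2492 and 41.8, and the interferon-induced gene Mx1 had 255 and 28.6, then 125 and 11.8. The prostaglandin synthase Ptgs2 had 351 and 1733, then 396 and 2288, and the adhesion gene Jam2 had 150 and 1198, then 265 and 1566.

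The cholesterol, ATF4 and glycolysis lists were all lower in the libraries labelled 4-OHT. Their highest median lay at -0.55 relative to the median of all genes. A scaling factor moves every gene of a library alike, so it would not set a list apart. These 3 lists were picked after the values were seen, for medians far from 0. Their distance was therefore no independent test of scaling. The values go against the trend on GC content and length, after whose removal the highest median was -0.59. A single aberrant 4-OHT library was not settled. In 3 of the 3 lists 4-OHT replicate 1 lay below both EtOH libraries, but the lists had been picked for their low medians. The 4 libraries allow only 3 splits into 2 and 2, too few for a share under 0.05; the real split gave 20 called lists, 1 of the 3 gave that many, and the highest other, between the replicate numbers, gave 9. That split also called 26 genes where the real one called 0, which points to a structure of the samples. A response to the 4-OHT treatment may underlie the lower lists, as a hypothesis found and tested on the same data. Fry called none of the lists. The test with an estimated correlation could not decide, since it called 0 of 5 simulated shifts. Without 4-OHT libraries from cells lacking floxed Mtor, the compound and Cre activity were not separated from loss of Mtor.

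The Mtor count was not lower in the libraries labelled 4-OHT. A deletion of few exons may remove only a small part of the counted length, since the largest exon makes up 9.8% of the longest annotated transcript. The labels do not name the deleted exons, and whether their loss changes the amount of the remaining transcript was not tested. Exchanged labels also stay open. Camera called 5 of 5 lists that mTORC1 is known to promote (cholesterol, fatty acid, glycolysis, hypoxia and ATF4) lower in the libraries labelled 4-OHT. These 5 lists were picked after the values were seen, so this was no independent test and no full tally of mTORC1 outputs. Cytosolic ribosomal proteins (median 0.03) and translation factors (median -0.01) were not called. Fry called none of the 5 lists, and the direction is background knowledge and not a measurement of Mtor. With an estimated correlation all 5 camera calls were lost at adjusted p = 0.495, but that test also called 0 of 5 simulated shifts. Counts per exon, not used here, would bear on both.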
